A study of Mus musculus with 12 samples.

How the data were processed

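Gene expression was measured in Kupffer cells of male C57BL/6 mice on 12 Illumina bead arrays, 2 in each of 6 groups (M0, LPS, IL-4, vehicle, SR3335 and SR1078). The groups were taken from the labels. The bead signals are intensity values, deposited as a table of 25697 probes without background subtraction or normalization between arrays, made by the authors with GenomeStudio 2011.1. Each signal has a detection p value, deposited beside it per the file headers, which compares the probe with negative control beads on the same array. The processed log2 values were quantile-normalized by the authors within 2 separate sets of 6 arrays, as the values themselves show. Quantile normalization of the deposited signals within each set gave the authors' values to within 0.011 log2 for 25667 probes, and 30 probes of the set with vehicle, SR3335 and SR1078 differed by 0.0605 to 2.32.

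The signals were analysed with limma 3.58.1 in R 4.3.3. They were background-corrected by the normexp method with negative control levels inferred from the detection p values, given an offset of 16, quantile-normalized over all 12 arrays and put on the log2 scale. Probes with a detection p under 0.05 on at least 2 arrays were kept (13678), and for genes with several kept probes (2470) the probe with the highest mean was used, which left 10255 genes, 9430 of them with a symbol. Symbols were matched by gene identifier to RefSeq genes for 23962 probes, and 1719 probes stayed unnamed. No genome build is given in the labels, so no positions are reported. Between 44.7% and 49.1% of probes were detected per array. The number of arrays limits precision.

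A linear model with 1 mean per group was fitted over all 12 arrays, with 6 residual degrees of freedom, and limma's moderated t-tests with Benjamini-Hochberg adjustment over all genes gave the adjusted p values. A gene passed at an adjusted p under 0.05. The 7 comparisons were LPS, IL-4 and vehicle with M0, LPS with IL-4, SR3335 and SR1078 with vehicle, and SR3335 with SR1078. With an array left out, a group of 1 array is assumed to vary like the other groups. Where a gene was undetected on both arrays of a group, its fold is a lower bound.

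There were 27 gene lists, each tested in limma by camera with a correlation of 0.01 between genes, and beside it with the correlation estimated from the data, adjusted over 189 tests. The lists were M1 inflammatory, M2, chemokine, interferon-stimulated, NF-kB feedback, MHC class II, MHC class I processing, Kupffer cell identity, clock, ROR-alpha target, LXR target, cholesterol synthesis, fatty acid oxidation and PPAR, respiratory chain, glycolysis and hypoxia, unfolded protein and integrated stress, NRF2 target, cell cycle, lysosome and immediate early genes, and markers of sinusoidal endothelium, hepatocytes, stellate cells and fibroblasts, T and NK cells, B cells, neutrophils, and dendritic cells and monocytes. Intervals of list means are 95% intervals from 1 mean per array. The 100 genes with the largest rise and the largest fall after LPS and after IL-4 were tested the same way in the comparisons of the compounds, with adjustment over those 12 tests. The comparisons, gene lists, tests, thresholds, alternative settings and the rule for naming genes were fixed before the data were examined. Tests described below as chosen later or not planned are exceptions.

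Genes were named by a rule. In each comparison these were the 10 genes with the largest rise and the 10 with the largest fall among those past the threshold whose 2 treated arrays both lay beyond both control arrays, then 2 to 4 members of each list, and Rora and Klf4 where measured. Genes without a symbol were left out. For 154 passing results of named genes another kept probe existed, and of these 213 other probe results 131 passed in the same direction, 82 did not pass and 0 passed in the opposite direction.

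Alternatives left out background correction, used another one, median centring, the authors' values, no filter or a stricter filter, every kept probe, a trend in the variance, array weights, only the compared groups, the replicate number as a block, or left out each array. Fits of each array set on its own and without the 30 differing probes were added after the data were seen. The linear fit and the list test, but not the earlier processing, were tried on simulated log2 values. In these, 200 genes were changed in SR1078 minus vehicle. The noise was independent between genes and had the fitted variance of each gene in all groups, so the outcome holds only under those assumptions. The fit recovered 29 of 67 genes changed by 0.5 log2, 63 of 67 changed by 1 and 65 of 66 changed by 2, and called 9 of 10030 unchanged genes. Genes of a further list, shifted to test the list method, are counted in neither group. Figures were drawn with matplotlib 3.10.9 and pandas 2.3.3 in Python 3.11.15.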

Results

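RNA of cultured mouse Kupffer cells, the resident macrophages of the liver, was measured on 12 Illumina bead arrays, in 6 groups of 2 arrays. The groups were cells without a named treatment (M0), cells given lipopolysaccharide (LPS, a bacterial surface component) at 10 ng/ml, cells given interleukin 4 (IL-4, a cytokine of type 2 immunity) at 20 ng/ml, cells given DMSO alone (vehicle), and cells given SR3335 or SR1078. The labels call LPS and IL-4 the M1 and M2 treatments. They describe SR3335 as an inverse agonist of the nuclear receptor ROR-alpha and SR1078 as a ROR agonist, and print their concentrations as 10 mM and 5 mM. The unit of these concentrations is in doubt, and nothing in the files allows it to be checked. The labels give 24 h for every group but M0, for which they give no time, so comparisons with M0 may also compare culture times. Each array held 25697 probes, of which 11474 to 12623 were detected, and 10255 genes were tested. Replicate arrays correlated across the genes tested at r = 0.9916 to 0.997, and the standard error (SE) of a log2 difference at the median spread was 0.123. The small number of arrays limits this precision. Nothing states that the arrays of a group came from separate cultures or animals, so p-values measure only the spread between these samples.

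The arrays formed 2 sets. M0, LPS and IL-4 had a background signal of 147 to 154, and vehicle, SR3335 and SR1078 had one of 88.9 to 99.1. Comparisons within a set are described first, and the comparison of vehicle with M0, which spans the sets, comes last. Values after ± are SEs of gene log2 differences between groups of 2 arrays. They rest on 1 moderated variance per gene, pooled over all groups, not on the groups compared alone. Replicate arrays differed with a standard deviation of 0.262 to 0.332 in M0, LPS and IL-4. In vehicle, SR3335 and SR1078 it was 0.194 to 0.207. The SEs and p-values may therefore be too small within the first set and too large within the second. All p-values are adjusted over all genes tested or, for gene lists, over all 189 list tests. In each of the 7 comparisons, every gene past the adjusted p of 0.05 had both arrays of 1 group beyond both of the other, an arrangement that chance gives to 33.3% of genes.

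The first comparison asked what LPS changes in Kupffer cells. Lcn2, which encodes the iron-scavenging protein lipocalin 2, rose 35.8-fold (log2 5.16 ± 0.23, n = 2 arrays per group, adjusted p = 1.63e-06). Ptges, an inducible prostaglandin E synthase, rose 21.9-fold (log2 4.45 ± 0.12, adjusted p = 1.9e-07). The alarmin gene S100a8 rose 24.1-fold (4.59 ± 0.15) and the acute phase gene Saa3 rose 8.56-fold (3.10 ± 0.08). Among the genes that fell were Pparg, a lipid-sensing nuclear receptor (-2.58 ± 0.10), Trem2, a lipid receptor (-2.56 ± 0.07), and Vsig4, a complement receptor of Kupffer cells (-1.92 ± 0.10). In all, 3110 of 10255 genes passed, 1381 higher and 1729 lower with LPS, and 530 of them differed at least 2-fold.

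Several of the largest differences involved genes not detected on either array of the dimmer group. Calb2, which encodes the calcium-binding protein calretinin, was at least 94.3-fold higher with LPS (adjusted p = 1.6e-07), and Serpinb2, a plasminogen activator inhibitor, at least 18.9-fold higher (adjusted p = 4.57e-07). Hpgd, which encodes a prostaglandin-degrading enzyme, was at least 10.3-fold lower (adjusted p = 1.76e-06), Dysf at least 5.4-fold lower and the cytokinesis gene Anln at least 4.28-fold lower. Slc7a2, an arginine transporter, rose by 3.77 ± 0.13 and Slamf1 by 3.62 ± 0.16. Nrp1 fell by 3.05 ± 0.11, the growth factor gene Igf1 by 2.68 ± 0.10 and Ciita, the master regulator of MHC class II, by 2.56 ± 0.15. Rora (0.27 ± 0.15, adjusted p = 0.21) and Klf4 (-0.31 ± 0.17, adjusted p = 0.2) did not pass.

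By gene list, 19 of 26 measured M1 inflammatory genes rose and 2 fell, a count that was the same when adjusted over the list alone (mean log2 1.21, list adjusted p = 5.44e-09, adjusted p = 0.0769 with an estimated correlation). Among chemokines, 10 of 14 rose and none fell, with Ccl7 at 1.68 ± 0.15 and Cxcl10 at 1.47 ± 0.07, and 10 passed when adjusted over the list alone (adjusted p = 4.88e-06, and adjusted p = 0.0662 with an estimated correlation). Interferon-stimulated genes rose in 15 of 26 cases, 15 also adjusted over the list alone, with Isg20 at 1.31 ± 0.14 and Isg15 at 1.10 ± 0.12 (adjusted p = 3.89e-07, and adjusted p = 0.0527 with an estimated correlation). NF-kB feedback genes rose in 10 of 17 cases and fell in 1, or 11 and 1 adjusted over the list alone, with Tnip1 at 1.50 ± 0.09 and Tnfaip3 at 1.11 ± 0.08 (adjusted p = 3.63e-05, and adjusted p = 0.102 with an estimated correlation). Glycolysis and hypoxia genes rose in 11 of 17 cases and fell in 2, or 12 and 2 adjusted over the list alone, with Hif1a at 1.32 ± 0.18 and Pfkl at 1.27 ± 0.07 (adjusted p = 4.22e-05, and adjusted p = 0.105 with an estimated correlation). NRF2 target genes, of the response to oxidants, rose in 6 of 12 cases, 6 also adjusted over the list alone, with Slc7a11 at 1.59 ± 0.11 and Gclm at 1.06 ± 0.13 (adjusted p = 0.00724, and adjusted p = 0.102 with an estimated correlation).

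Cell cycle genes fell in 17 of 26 cases and rose in 1, or 18 and 1 adjusted over the list alone, with Plk1 at -1.59 ± 0.09 and Birc5 at -1.44 ± 0.10 (mean -0.65, adjusted p = 4.59e-06, and adjusted p = 0.0575 with an estimated correlation). Kupffer cell identity genes fell in 12 of 20 cases and rose in 3, also adjusted over the list alone, with Clec1b at -2.25 ± 0.18 and C1qc at -1.41 ± 0.09 (adjusted p = 0.000518, and adjusted p = 0.105 with an estimated correlation). LXR target genes, of sterol export and lipid synthesis, fell in 5 of 11 cases, or 6 adjusted over the list alone, with Abcg1 at -1.33 ± 0.11 and Scd1 at -1.89 ± 0.17 (adjusted p = 0.00732, and adjusted p = 0.102 with an estimated correlation). Cholesterol synthesis genes fell in 5 of 14 cases and rose in 1, also adjusted over the list alone, with Sqle at -1.33 ± 0.13 and Dhcr7 at -1.07 ± 0.12. That list had adjusted p = 0.0377, and adjusted p = 0.155 with an estimated correlation, and without LPS replicate 2 it did not pass (adjusted p = 0.0608). M2 genes went both ways, with 5 of 30 higher and 8 lower, also adjusted over the list alone (mean -0.17, adjusted p = 0.412). Arg1, the arginine-degrading enzyme, rose by 2.75 ± 0.16, and the mannose receptor gene Mrc1 fell by 1.93 ± 0.09.

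The remaining lists did not pass after LPS. Their mean log2 differences were -0.22 for MHC class II, 0.16 for MHC class I processing, 0.15 for clock genes, 0.28 for genes described as ROR-alpha targets, -0.24 for fatty acid oxidation and PPAR genes, -0.09 for the respiratory chain, -0.20 for lysosome genes and 0.11 for immediate early genes. Unfolded protein and integrated stress genes had a mean of 0.13 but a median of -0.02. Among markers of other liver cells, the mean was -0.42 for sinusoidal endothelium (adjusted p = 0.0541), -0.17 for T and NK cells, -0.15 for B cells, 0.74 for neutrophils and -0.13 for dendritic cells and monocytes. Hepatocyte markers had a mean of 0.02 and a median of -0.06, and stellate cell and fibroblast markers a mean of 0.11 and a median of 0.00. The split of the LPS calls depended on scaling, since median centring in place of quantile normalization moved the median of all genes to -0.132 and gave 952 higher and 2641 lower (26.5% higher against 44.4%).

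**Figure D1:**
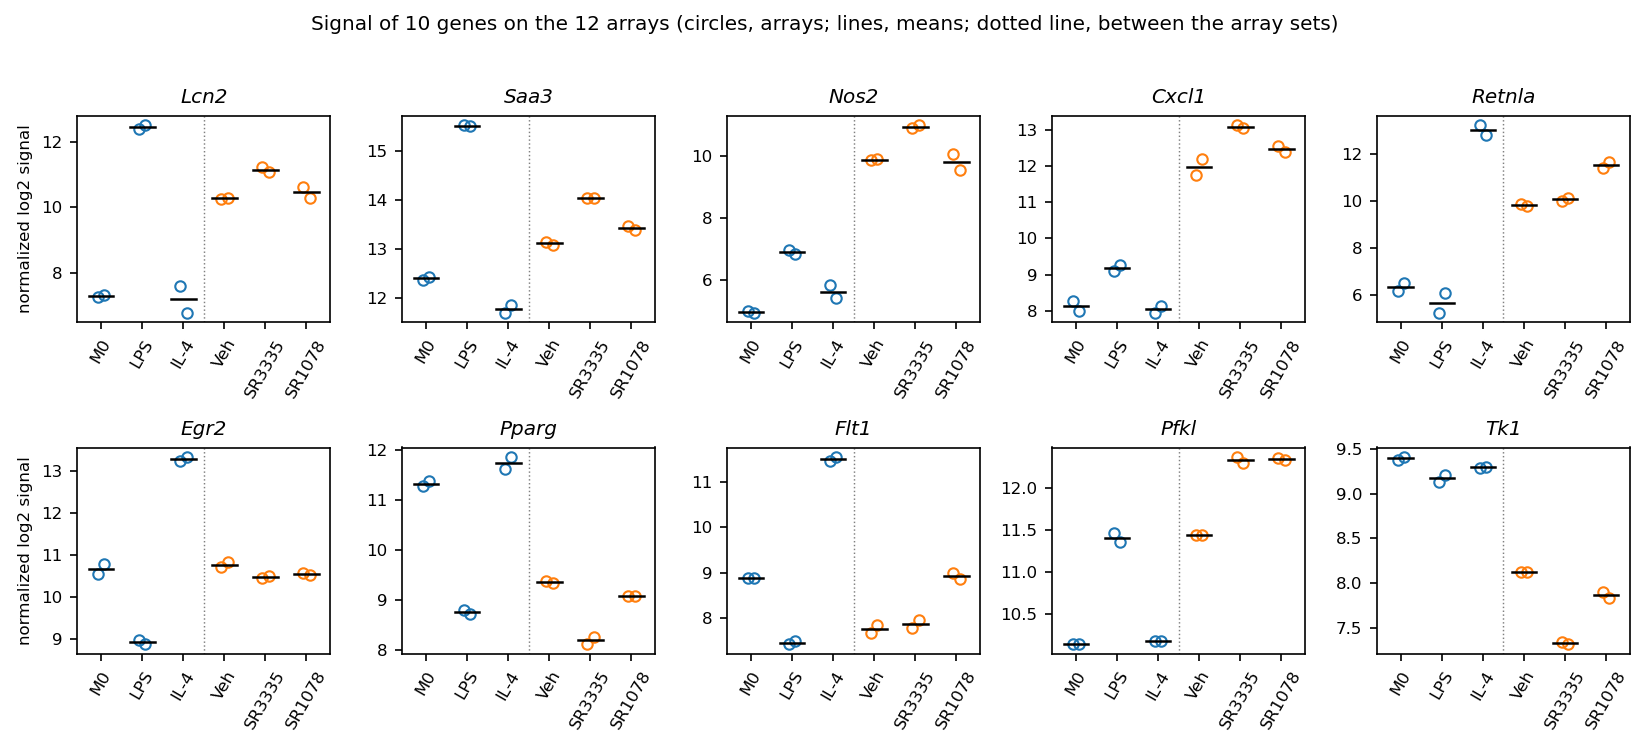
Normalized log2 signal (y axis) of 10 genes on each of the 12 arrays, by group (x axis), with circles for arrays, a line for each group mean, and a dotted line between the 2 array sets. Lcn2 lies at 12.45 on average with LPS and 7.29 in M0, Retnla at 13.02 with IL-4 and 6.33 in M0, and Pfkl at 12.33 with SR3335, 12.34 with SR1078 and 11.44 with vehicle.

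IL-4 was compared with M0 to ask what the M2 treatment changes. Retnla, which encodes a secreted protein of type 2 responses, rose 103-fold (log2 6.69 ± 0.26, n = 2 arrays per group, adjusted p = 1.69e-06). Rnase2a, an eosinophil-type ribonuclease gene, was undetected on both M0 arrays and at least 54.9-fold higher with IL-4 (adjusted p = 2.42e-07), and Pdcd1lg2, which encodes the checkpoint ligand PD-L2, at least 11-fold higher (adjusted p = 3.25e-05). The chemokine gene Ccl24 rose by 4.03 ± 0.14, Arg1 by 3.29 ± 0.16 and Chil3, a chitinase-like protein gene, by 3.11 ± 0.20. In all, 2007 genes passed, 868 higher and 1139 lower, and 222 differed at least 2-fold.

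M2 genes rose in 25 of 30 measured cases and none fell, also adjusted over the list alone (mean log2 1.91, adjusted p = 1.02e-23). This call held with an estimated correlation (adjusted p = 0.00509). Beyond that list, Slc7a2, listed among the M1 genes, rose by 4.03 ± 0.13, Ear10 by 3.24 ± 0.15, the chemokine gene Ccl8 by 2.65 ± 0.09 and Flt1, a receptor for vascular growth factors, by 2.63 ± 0.10. Klf4, a transcription factor gene, rose by 1.50 ± 0.17 (adjusted p = 0.000664), and Rora fell by 0.56 ± 0.15 (adjusted p = 0.0321). The Rora call was lost without M0 replicate 1 (-0.54, adjusted p = 0.124), M0 replicate 2 (-0.59, adjusted p = 0.0943) or IL-4 replicate 1 (-0.45, adjusted p = 0.15). The falls were smaller than the rises. Clec4n, a C-type lectin gene, fell by 1.96 ± 0.10, Ifitm6 by 2.28 ± 0.21 and Sdc2 by 1.76 ± 0.17. Abca9, undetected with IL-4, was at least 3.23-fold lower (adjusted p = 6.66e-05). The other kept probe of this gene gave 0.01.

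Of 26 interferon-stimulated genes, 7 rose and 1 fell, or 8 and 2 adjusted over the list alone, with Ifih1, undetected in M0, at least 1.47-fold higher (mean 0.14, adjusted p = 0.0208, and adjusted p = 0.128 with an estimated correlation). MHC class II genes rose in 3 of 10 cases, also adjusted over the list alone, with H2-Aa at 0.67 ± 0.10 and H2-DMa at 0.53 ± 0.09 (adjusted p = 0.0279, and adjusted p = 0.369 with an estimated correlation). Unfolded protein and integrated stress genes rose in 7 of 24 cases and fell in 3, or 10 and 3 adjusted over the list alone, with the serine synthesis gene Psat1 at 1.76 ± 0.11 (adjusted p = 0.0154, and adjusted p = 0.104 with an estimated correlation). Cell cycle genes rose in 8 of 26 cases and fell in 1, or 9 and 2 adjusted over the list alone, with Ccnd1 at 0.91 ± 0.09 and Mcm6 at 0.77 ± 0.10 (adjusted p = 0.0399, and adjusted p = 0.201 with an estimated correlation). T and NK cell markers fell in 6 of 10 cases, or 7 adjusted over the list alone, with Cd2 at -0.82 ± 0.10 and Cd3g at -0.64 ± 0.10 (mean -0.37, adjusted p = 0.00674, and adjusted p = 0.201 with an estimated correlation). Sinusoidal endothelial markers rose in 5 of 18 cases and fell in 2, also adjusted over the list alone, with Dnase1l3 at 1.23 ± 0.11 (adjusted p = 0.0282, and adjusted p = 0.328 with an estimated correlation).

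M1 inflammatory genes (4 of 26 higher and 9 lower, mean -0.05, adjusted p = 0.164) and chemokines (6 of 14 higher and 4 lower, mean 0.50, adjusted p = 0.1) did not pass as lists, with the same counts adjusted over the list alone. Within them, Fpr2, a formyl peptide receptor gene, fell by 1.39 ± 0.12, and Ccl7 rose by 2.18 ± 0.15 and Ccl2 by 1.51 ± 0.16. The number of genes past the threshold was 1069 without M0 replicate 1, 1143 without M0 replicate 2 and 1333 without IL-4 replicate 1. Each of these arrays also ended list calls, leaving interferon-stimulated genes at adjusted p = 0.0655 and MHC class II genes at adjusted p = 0.173 without IL-4 replicate 1, MHC class II genes at adjusted p = 0.0812 and cell cycle genes at adjusted p = 0.2 without M0 replicate 1, and interferon-stimulated genes at adjusted p = 0.0521 and endothelial markers at adjusted p = 0.106 without M0 replicate 2. Without IL-4 replicate 2, cell cycle genes (adjusted p = 0.152) and endothelial markers (adjusted p = 0.24) did not pass. Median centring gave 684 higher and 1438 lower (32.2% higher against 43.2%).

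LPS and IL-4 were also set against each other, the contrast between the M1 and M2 treatments. Egr2, a transcription factor gene, was 20.6-fold lower with LPS than with IL-4 (log2 -4.36 ± 0.10, n = 2 arrays per group, adjusted p = 3.41e-08), and Retnla was 165-fold lower (-7.36 ± 0.26, adjusted p = 2.65e-07). The lectin receptor gene Clec4e was 12.2-fold higher with LPS (3.61 ± 0.09, adjusted p = 5.42e-08), Trem3, an activating receptor gene, 23.9-fold higher (4.58 ± 0.08) and Saa3 13.2-fold higher (3.72 ± 0.08). Ptges, undetected with IL-4, was at least 38.5-fold higher with LPS (adjusted p = 3.41e-08). In all, 3742 genes passed, 1850 higher and 1892 lower with LPS. Rora was higher with LPS (0.84 ± 0.15, adjusted p = 0.00273) and Klf4 lower (-1.81 ± 0.17, adjusted p = 6.32e-05).

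M2 genes were lower with LPS in 21 of 30 cases and higher in 2, or 22 and 3 adjusted over the list alone (mean -2.08, adjusted p = 2.01e-11), and this call held with an estimated correlation (adjusted p = 0.022). M1 inflammatory genes were higher in 17 of 26 cases and lower in 2, also adjusted over the list alone, with Socs3 at 2.75 ± 0.10 (mean 1.26, adjusted p = 8.37e-07, and adjusted p = 0.102 with an estimated correlation). NF-kB feedback genes were higher in 12 of 17 cases, also adjusted over the list alone, with Tnip1 at 1.86 ± 0.09 (adjusted p = 5.67e-06, and adjusted p = 0.0977 with an estimated correlation). Cell cycle genes were lower in 17 of 26 cases and 1 more was higher adjusted over the list alone, where 19 were lower, with Ccnd1 at -2.24 ± 0.09 (mean -0.79, adjusted p = 7.05e-08, and adjusted p = 0.0529 with an estimated correlation). Kupffer cell identity genes were lower in 13 of 20 cases and higher in 3, also adjusted over the list alone, and went apart, with Vsig4 at -2.33 ± 0.10 and Spic, a transcription factor gene of iron-recycling macrophages, at 2.35 ± 0.10 (adjusted p = 0.000364, and adjusted p = 0.103 with an estimated correlation). NRF2 target genes were higher in 8 of 12 cases, also adjusted over the list alone, with Slc7a11 at 2.17 ± 0.11 (adjusted p = 0.000559, and adjusted p = 0.0739 with an estimated correlation). MHC class II genes were lower in 7 of 10 cases and higher in 2, also adjusted over the list alone, with Ciita at -2.42 ± 0.15 (adjusted p = 0.0328, adjusted p = 0.385 with an estimated correlation, and adjusted p = 0.0862 without IL-4 replicate 1).

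Sinusoidal endothelial markers were lower with LPS in 10 of 18 cases and higher in 1, or 11 and 1 adjusted over the list alone, with Stab2 at -1.55 ± 0.10 and Oit3 at -1.53 ± 0.14 (mean -0.62, adjusted p = 0.000315, and adjusted p = 0.16 with an estimated correlation). LXR target genes were lower in 5 of 11 cases, also adjusted over the list alone, with Scd1 at -2.04 ± 0.17 (mean -0.58, adjusted p = 0.00572, and adjusted p = 0.102 with an estimated correlation). Glycolysis and hypoxia genes were higher in 11 of 17 cases and lower in 3, or 12 and 3 adjusted over the list alone, with Tpi1 at 1.26 ± 0.08 and Pfkp at -1.56 ± 0.13 (mean 0.42, adjusted p = 0.00339, and adjusted p = 0.197 with an estimated correlation). Interferon-stimulated genes were higher in 11 of 26 cases and lower in 1, or 13 and 1 adjusted over the list alone, with Isg20 at 1.30 ± 0.14 (mean 0.33, adjusted p = 0.00145, and adjusted p = 0.0769 with an estimated correlation). Chemokines were higher in 9 of 14 cases and lower in 4, or 10 and 4 adjusted over the list alone, with Cxcl10 at 2.08 ± 0.07 and Ccl8 at -1.91 ± 0.09 (mean 0.27, adjusted p = 0.0359, and adjusted p = 0.209 with an estimated correlation). The chemokine call was lost without LPS replicate 2 (adjusted p = 0.0615) or IL-4 replicate 2 (adjusted p = 0.112). Neutrophil markers had a mean of 0.87 and did not pass (2 of 6 higher and 1 lower, or 3 and 1 adjusted over the list alone, adjusted p = 0.306).

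Across all 10255 genes, the LPS and IL-4 differences from M0 correlated at r = 0.19 (Spearman rho 0.24). They share the M0 arrays, which alone gave r = 0.5 in 100 simulations without any effect. The covariance is therefore the measure to compare, at 0.039 against 0.0129 in the simulations. Those simulations used the spread pooled over all groups, so 0.0129 may be too low for the M0 arrays. Genes are not independent replicates. Median centring gave 1368 higher and 2270 lower with LPS (37.6% higher against 49.4%).

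The comparison of SR3335 with vehicle asked what the compound labelled an inverse agonist changes. Ptges rose 2.15-fold (log2 1.10 ± 0.12, n = 2 arrays per group, adjusted p = 0.00222) and Saa3 1.89-fold (0.92 ± 0.08, adjusted p = 0.00121), and Pfkl, the liver-type phosphofructokinase of glycolysis, rose 1.85-fold (0.89 ± 0.07, adjusted p = 0.0012). Calb2 rose 3.76-fold (1.91 ± 0.18), Mgarp, a mitochondrial protein gene, 3.3-fold (1.72 ± 0.13) and the cytokine gene Il19 3.1-fold (1.63 ± 0.12). Pparg fell by 1.16 ± 0.10, the elastase gene Cela1 by 1.57 ± 0.13 and the thymidine kinase gene Tk1 by 0.80 ± 0.07. In all, 475 genes passed, 214 higher and 261 lower, and 49 differed at least 2-fold. Which direction held more genes depended on how the values were made. More were lower under median centring (166 higher and 262 lower), and more were higher without background correction (383 and 346) and in the authors' values (497 and 451).

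Rora itself was lower with SR3335 (-1.68 ± 0.15, adjusted p = 0.00127), but its values are among those of 30 probes that differ between the deposited signals and the authors' processed table. That table gives a log2 difference of -0.74. Its values lack the background correction used here, so differences from the 2 tables, here and below, are not made alike. On the SR3335 arrays Rora had signals of 123.17 and 134.09, with detection p of 0.0388 and 0.0439. Probes of the nearest signals had 0.134 and 0.0539, above the 0.05 limit for detection. Judged by its signal, Rora was near the background there, so the size of this fall is uncertain. Klf4 did not pass (0.20 ± 0.17, adjusted p = 0.62, and 0.18 in the authors' table). Its other kept probes were lower there, at -1.05 (adjusted p = 0.00313, and -0.47 in the authors' table) and -1.50 (adjusted p = 0.00401, and -0.68 in the authors' table). All 3 are among the differing probes. None of the other genes named for this comparison is. Among further rises were Sprr2d (1.56 ± 0.15), Sema4f (1.54 ± 0.16) and the adenylate kinase gene Ak4 (1.39 ± 0.12). Il5, undetected on both vehicle arrays, was at least 2.42-fold higher (adjusted p = 0.00443). Further falls were Sirpb1a (-1.35 ± 0.13), Rbfox3 (-1.19 ± 0.10), Btbd11 (-1.18 ± 0.11) and the condensin gene Ncapg2 (-1.15 ± 0.10). The lymphocyte cytokine gene Ifng was higher by 1.62 ± 0.24 (adjusted p = 0.00835), but with any 1 of the 4 arrays left out its adjusted p lay between 0.0505 and 0.0773. Without SR3335 replicate 1, Il5 had adjusted p = 0.0507.

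Glycolysis and hypoxia genes rose in 8 of 17 cases, or 13 adjusted over the list alone, and none fell, with the glucose transporter gene Slc2a1 at 0.62 ± 0.08 and Ndrg1 at 0.72 ± 0.13 (mean 0.52, 95% interval 0.39 to 0.66, adjusted p = 3.19e-13, and adjusted p = 0.0529 with an estimated correlation). M1 inflammatory genes rose in 7 of 26 cases, or 12 adjusted over the list alone, with Nos2, the inducible nitric oxide synthase, at 1.07 ± 0.18 (mean 0.39, 95% interval 0.27 to 0.52, adjusted p = 1.22e-08, and adjusted p = 0.0769 with an estimated correlation). Of 14 chemokines 3 rose and 1 fell, or 3 and 2 adjusted over the list alone, with Cxcl9 at 0.63 ± 0.07 and Ccl6 at -0.97 ± 0.12 (mean 0.07, adjusted p = 0.453). M2 genes did not pass as a list, with 2 of 30 lower, Pparg and Mgl2, or 2 higher and 2 lower adjusted over the list alone (mean -0.04, median 0.01, adjusted p = 0.929). Cell cycle genes fell in 4 of 26 cases, or 6 adjusted over the list alone where 1 rose (mean -0.24, adjusted p = 7.31e-05, and adjusted p = 0.0739 with an estimated correlation). Kupffer cell identity genes had a mean of -0.22 with 1 of 20 lower, Clec1b at -0.93 ± 0.18, or 2 adjusted over the list alone (adjusted p = 2.03e-05, and adjusted p = 0.0769 with an estimated correlation). LXR target genes had a mean of -0.18 with 1 of 11 lower, the lipoprotein lipase gene Lpl at -0.77 ± 0.09, and 1 also adjusted over the list alone (adjusted p = 0.0178, and adjusted p = 0.123 with an estimated correlation). NF-kB feedback genes (mean 0.15, 2 of 17 higher, adjusted p = 0.00164, and adjusted p = 0.161 with an estimated correlation) also passed, with 5 higher adjusted over the list alone. NRF2 target genes had a mean of 0.22 with 2 of 12 higher, also adjusted over the list alone (adjusted p = 0.0178, adjusted p = 0.123 with an estimated correlation, and adjusted p = 0.0611 without SR3335 replicate 2). Fatty acid oxidation and PPAR genes had a mean of -0.17 with 1 of 12 lower, or 3 adjusted over the list alone (adjusted p = 0.014, adjusted p = 0.204 with an estimated correlation, and adjusted p = 0.0736 without SR3335 replicate 2). Unfolded protein and integrated stress genes had a mean of 0.10 with 1 of 24 higher, also adjusted over the list alone (adjusted p = 0.0399, and adjusted p = 0.149 with an estimated correlation). They did not pass without vehicle replicate 2 (adjusted p = 0.117) or SR3335 replicate 2 (adjusted p = 0.0991). Hepatocyte markers had a mean of 0.27 with 0 of 16 past the threshold, also adjusted over the list alone (adjusted p = 0.0291, and adjusted p = 0.556 with an estimated correlation). They did not pass without SR3335 replicate 1 (mean 0.06, adjusted p = 0.611) or vehicle replicate 1 (0.20, adjusted p = 0.148). Genes described as ROR-alpha targets (mean 0.10, 1 of 10 lower, adjusted p = 0.359) and clock genes (mean -0.03, median 0.15, 2 of 15 lower, adjusted p = 0.521) did not pass, with 1 lower and with 2 higher and 2 lower adjusted over the list alone. The lower clock genes were Rora, whose probe differs between the tables, and Per2 (-0.59), whose other kept probe gave 0.17.

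The 100 genes with the largest rise after LPS, a list chosen on the other array set, had a mean of 0.37 in SR3335 minus vehicle, with 27 higher and none lower (adjusted p = 9.12e-18). The 100 with the largest fall after LPS had a mean of -0.28, with 22 lower and 1 higher (adjusted p = 7.44e-11). Both calls held with an estimated correlation (adjusted p = 0.00171 and adjusted p = 0.0051). The 100 genes most raised by IL-4 did not shift detectably (mean 0.01, median -0.03, adjusted p = 0.877). The 100 most lowered by IL-4 had a mean of -0.20 (adjusted p = 2.88e-06, and adjusted p = 0.444 with an estimated correlation). Across genes, the SR3335 difference correlated with that of LPS at r = 0.28 (rho 0.21) and with that of IL-4 at r = 0.10 (rho 0.09).

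The number of genes past the threshold fell when any of the 4 arrays was left out, to 76 without vehicle replicate 1, 143 without vehicle replicate 2, 94 without SR3335 replicate 1 and 120 without SR3335 replicate 2. Of the 51 named genes past the threshold, 21 passed without each array in turn, while Slc2a1 (adjusted p = 0.0523) and Ccl6 (adjusted p = 0.0502) did not pass without vehicle replicate 1. Nos2, Mgl2, Ndrg1 and Clec1b did not pass without vehicle replicate 1, vehicle replicate 2, SR3335 replicate 1 or SR3335 replicate 2 (adjusted p from 0.0509 to 0.246).

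**Figure D2:**
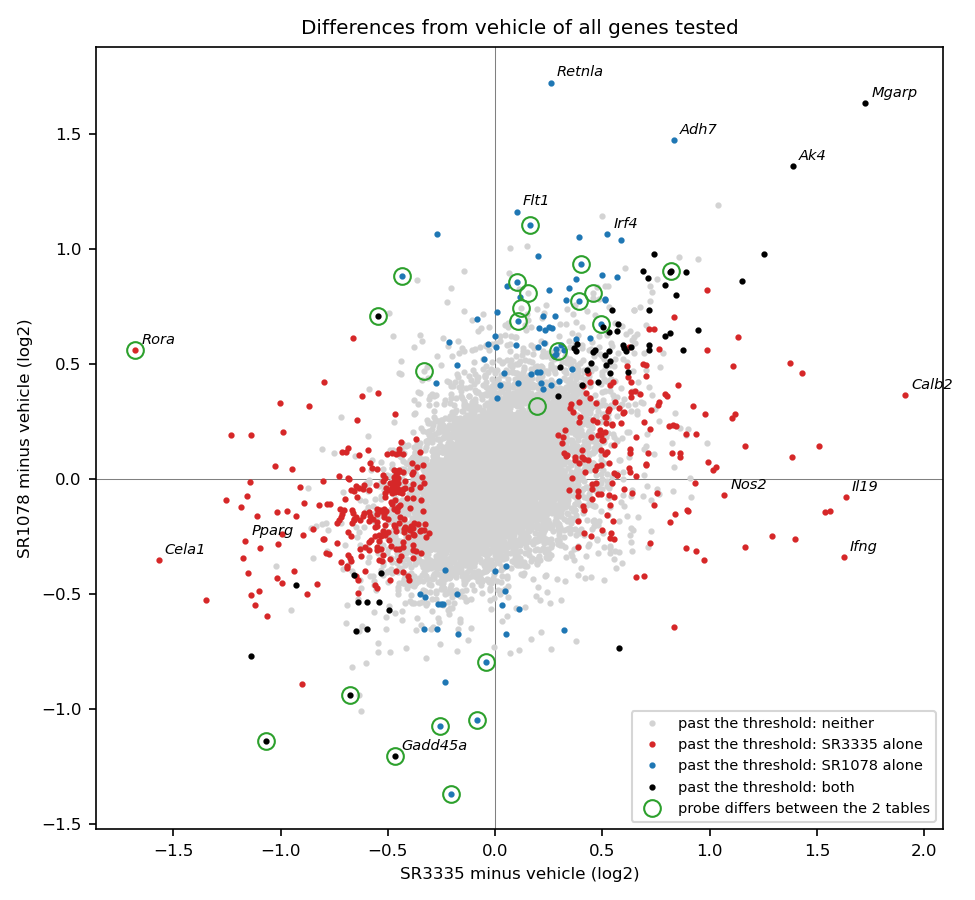
Log2 difference of SR3335 from vehicle (x axis) against that of SR1078 from vehicle (y axis) for all 10255 genes tested, with points coloured by the comparison in which the gene passed and green rings on probes that differ between the 2 deposited tables. Mgarp lies at 1.72 and 1.63, Calb2 at 1.91 and 0.36, and Rora, which is ringed, at -1.68 and 0.56.

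SR1078 was compared with vehicle to ask what the compound labelled a ROR agonist changes. Flt1 rose 2.24-fold (log2 1.16 ± 0.10, n = 2 arrays per group, adjusted p = 0.00385) and Retnla 3.3-fold (1.72 ± 0.26, adjusted p = 0.0192), both also raised by IL-4 in the other array set. Mgarp rose 3.1-fold (1.63 ± 0.13, adjusted p = 0.00385), Ak4 2.56-fold (1.36 ± 0.12) and Pfkl 1.87-fold (0.90 ± 0.07, adjusted p = 0.00385). Irf4, a transcription factor gene of M2 macrophages, rose by 1.06 ± 0.13, Adh7 by 1.47 ± 0.28 and Eml1 by 1.07 ± 0.12. The hormone gene Sct fell by 0.88 ± 0.14 and the cohesin gene Smc1b by 0.77 ± 0.11. In all, 144 genes passed, 108 higher and 36 lower, and 15 differed at least 2-fold. Flt1, Mgarp and Pfkl passed whichever array was left out. Retnla, Irf4, Adh7, Eml1, Sct and Smc1b did not pass without vehicle replicate 1, vehicle replicate 2, SR1078 replicate 1 or SR1078 replicate 2 (adjusted p from 0.0563 to 0.277), nor did Ak4 without vehicle replicate 1 (adjusted p = 0.059) or vehicle replicate 2 (adjusted p = 0.056).

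Among the genes whose probes differ between the deposited tables, 16 passed here, and the following values give the background-corrected signals first. Gadd45a, a growth arrest gene, had a difference of -1.20 ± 0.10 (-1.20 in the authors' table), although its other kept probe gave 0.04. Aldh1b1 had -1.37 ± 0.16 (-0.59 in the authors' table), Nuak1 -1.14 ± 0.20 (-0.60), Nfkbiz -1.07 ± 0.13 (-0.88), Clec4g -1.05 ± 0.14 (-0.62), Arap3 -0.94 ± 0.14 (-0.66) and the clock output gene Dbp -0.80 ± 0.11 (-0.79). The kinase gene Matk had 1.10 ± 0.11 (1.23 in the authors' table), Mrc1 0.86 ± 0.09 (1.08) and Ccl24 0.93 ± 0.14 (0.94). Rora (0.56 ± 0.15, adjusted p = 0.122, 0.56 in the authors' table) and Klf4 (0.32 ± 0.17, adjusted p = 0.432, 0.41 in the authors' table) did not pass. The other kept probes of Klf4 gave 0.60 ± 0.12 (adjusted p = 0.0586, 0.56 in the authors' table) and 1.19 ± 0.18 (adjusted p = 0.0242, 0.89 in the authors' table). Without the differing probes, 107 genes passed, 85 higher and 22 lower, all 107 of them among the 144. Gadd45a passed whichever array was left out. The 9 other genes named in this paragraph as passing, not all that passed, were lost without vehicle replicate 2 or SR1078 replicate 2. They were also lost without vehicle replicate 1, except Matk, and without SR1078 replicate 1, except Mrc1.

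**Figure D3:**
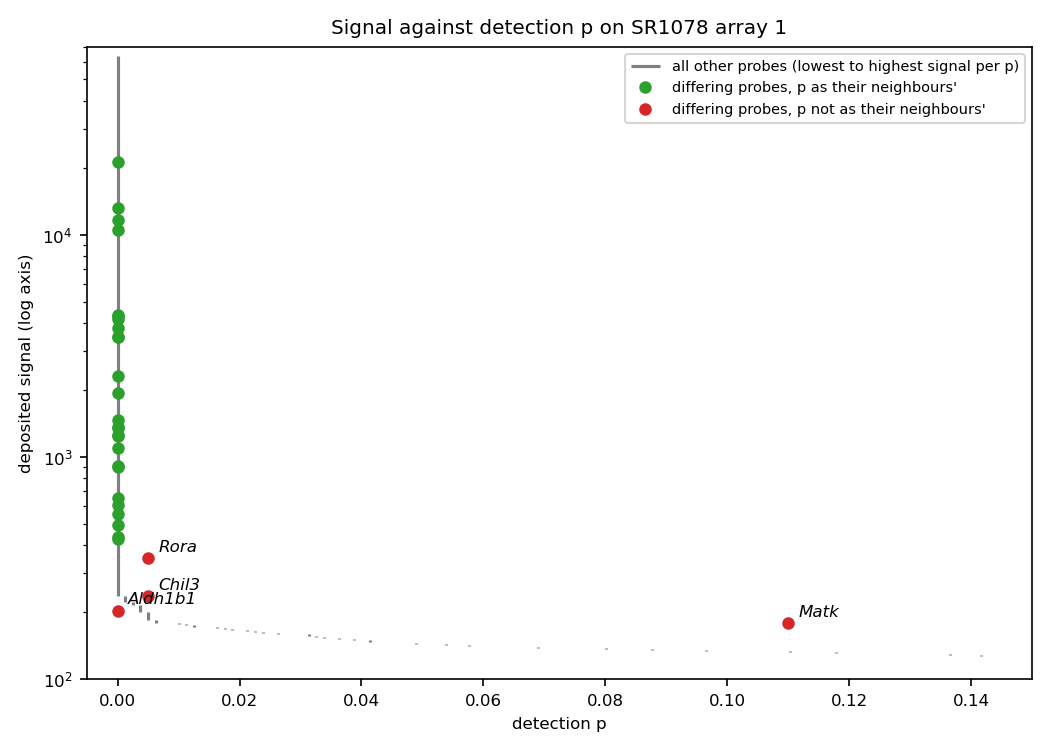
Signal (y axis, log scale) against detection p value (x axis) on array 1 of SR1078, with grey lines for the range of all other probes at each p and red points for probes of Rora, Chil3, Aldh1b1 and Matk. The Rora point has a signal of 350 at a detection p of 0.00501, where other probes had signals of 185 to 200.9.

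Glycolysis and hypoxia genes rose in 6 of 17 cases, or 14 adjusted over the list alone, with the triosephosphate isomerase gene Tpi1 at 0.56 ± 0.08 (mean 0.46, 95% interval 0.32 to 0.59, adjusted p = 7.2e-12, and adjusted p = 0.0575 with an estimated correlation). Cell cycle genes fell in 2 of 26 cases, Tpx2 and Birc5, or 8 adjusted over the list alone (mean -0.23, adjusted p = 4.59e-06, and adjusted p = 0.0575 with an estimated correlation). Of the NRF2 target genes 1 of 12 rose, Srxn1 at 0.56 ± 0.08, or 3 adjusted over the list alone (mean 0.31, adjusted p = 0.000145, and adjusted p = 0.0662 with an estimated correlation). Kupffer cell identity genes had a mean of -0.09 with 0 of 20 past the threshold, also adjusted over the list alone (adjusted p = 0.0316, and adjusted p = 0.234 with an estimated correlation). They did not pass without vehicle replicate 1 (adjusted p = 0.054), vehicle replicate 2 (adjusted p = 0.0575) or SR1078 replicate 2 (adjusted p = 0.147). Cholesterol synthesis genes had a mean of -0.20 with 1 of 14 lower, Lss at -0.65 ± 0.10, or 3 adjusted over the list alone (adjusted p = 0.00157, and adjusted p = 0.0769 with an estimated correlation). Interferon-stimulated genes had a mean of -0.15 with 0 of 26 past the threshold, also adjusted over the list alone (adjusted p = 0.000204, and adjusted p = 0.0686 with an estimated correlation). NF-kB feedback genes had a mean of -0.16 with 1 of 17 lower, or 1 higher and 1 lower adjusted over the list alone (95% interval -0.27 to -0.05, adjusted p = 0.0104, and adjusted p = 0.223 with an estimated correlation). Without the list members whose probes differ between the tables that mean was -0.10. B cell markers had a mean of 0.46 with 1 of 6 higher, Cd79b at 0.62 ± 0.10, or 4 adjusted over the list alone (adjusted p = 0.00229, and adjusted p = 0.158 with an estimated correlation). Stellate cell and fibroblast markers had a mean of 0.21 (95% interval 0.13 to 0.29) and did not pass, with 0 of 9 past the threshold, or 1 higher adjusted over the list alone (adjusted p = 0.108). Hepatocyte markers had a mean of 0.25 with 0 of 16 past the threshold, also adjusted over the list alone (adjusted p = 0.0178, and adjusted p = 0.528 with an estimated correlation). They did not pass without vehicle replicate 1 (adjusted p = 0.118) or SR1078 replicate 1 (adjusted p = 0.352). The single genes Tpi1, Tpx2, Birc5, Srxn1, Lss and Cd79b did not pass without vehicle replicate 1, vehicle replicate 2, SR1078 replicate 1 or SR1078 replicate 2 (adjusted p from 0.0677 to 0.287).

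M2 genes did not pass as a list, with 4 of 30 higher, or 6 higher and 1 lower adjusted over the list alone (mean 0.16, 95% interval 0.07 to 0.25, adjusted p = 0.188). The 4 were Retnla, Irf4, Mrc1 and Ccl24, and without the 5 list members whose probes differ between the tables the mean was 0.05. M1 inflammatory genes had 0 of 26 past the threshold, or 2 higher and 4 lower adjusted over the list alone (mean -0.09, 95% interval -0.21 to 0.04, adjusted p = 0.0906). They passed as a list of lower genes without SR1078 replicate 1 (mean -0.14, adjusted p = 0.0207). Neither the 100 genes most raised by LPS (mean -0.01, median 0.02, adjusted p = 0.62) nor the 100 most lowered by it (mean 0.01, median -0.05, adjusted p = 0.539) shifted detectably. Of the 100 genes most raised by IL-4, 13 have probes that differ between the tables, and without the differing probes the mean of this list was 0.03 (adjusted p = 0.923). With them the 100 genes had a mean of 0.11 with 11 higher and 1 lower (adjusted p = 0.0572, and adjusted p = 0.676 with an estimated correlation). Their mean was 0.13 without vehicle replicate 2 and 0.11 without SR1078 replicate 2. The 100 most lowered had a mean of -0.10 (adjusted p = 0.00418, and adjusted p = 0.676 with an estimated correlation). Across genes, the SR1078 difference correlated with that of LPS at r = -0.05 (rho -0.08) and with that of IL-4 at r = 0.11 (rho 0.07).

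This comparison rested on all 4 arrays. With 1 array left out, 5 genes passed without vehicle replicate 1, 5 without vehicle replicate 2, 6 without SR1078 replicate 1 and 8 without SR1078 replicate 2. Of the 35 named genes past the threshold Flt1, Gadd45a, Mgarp and Pfkl passed each time. Median centring gave 103 higher and 21 lower and the authors' values 333 and 187 (83.1% and 64% higher against 75%).

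The compounds were compared with each other directly, although the concentrations differ as printed, 10 mM for SR3335 and 5 mM for SR1078. Il27, a cytokine subunit gene, was 2.04-fold higher than with SR1078 (log2 1.03 ± 0.13, n = 2 arrays per group, adjusted p = 0.0051), Nos2 2.2-fold (1.14 ± 0.18, adjusted p = 0.0115) and Ptges 1.79-fold (0.84 ± 0.12, adjusted p = 0.00747). Ifng was higher by 1.97 ± 0.24, Il19 by 1.71 ± 0.12 and Calb2 by 1.55 ± 0.18. Retnla was lower with SR3335 (-1.46 ± 0.26), as were Pparg (-0.89 ± 0.10), the nucleic acid sensor gene Tlr13 (-1.32 ± 0.12) and the chemokine gene Xcl1 (-1.33 ± 0.11). In all, 471 genes passed, 216 higher and 255 lower with SR3335. Without SR3335 replicate 1, Il27 (adjusted p = 0.0552), Nos2 (adjusted p = 0.0851), Ptges (adjusted p = 0.0835), Ifng (adjusted p = 0.0532) and Retnla (adjusted p = 0.115) did not pass. Neither did they without SR1078 replicate 2 (adjusted p from 0.0523 to 0.137), nor Nos2 (adjusted p = 0.0763) and Retnla (adjusted p = 0.0822) without SR3335 replicate 2, nor Retnla without SR1078 replicate 1 (adjusted p = 0.0782).

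Rora was lower with SR3335 than with SR1078 (-2.24 ± 0.15, adjusted p = 0.00122, -1.31 in the authors' table), as were Igf1 (-1.25 ± 0.10, -1.37 in the authors' table) and Mrc1 (-0.76 ± 0.09, -0.72 in the authors' table), and the probes of these 3 genes differ between the tables. The size of the Rora difference is uncertain here too, since its SR3335 signals were near the background. The probe used for Klf4 did not pass (-0.12 ± 0.17, adjusted p = 0.789, -0.23 in the authors' table). Its other kept probes were lower, at -1.65 ± 0.12 and -2.69 ± 0.18 (adjusted p = 0.000885 for both, and -1.03 and -1.57 in the authors' table). Other genes higher with SR3335 were Sprr2d (1.70 ± 0.15), Sema4f (1.68 ± 0.16), Gpr83 (1.66 ± 0.19), Tacr2 (1.54 ± 0.12), Rnf225 (1.48 ± 0.17) and the keratin gene Krt16 (1.46 ± 0.16). Lower ones were Eml1 (-1.33 ± 0.12), Cyp4b1 (-1.27 ± 0.13) and Acot4 (-1.22 ± 0.14).

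M1 inflammatory genes were higher with SR3335 in 9 of 26 cases, or 21 and 1 lower adjusted over the list alone (mean 0.48, 95% interval 0.35 to 0.60, adjusted p = 8.02e-13, and adjusted p = 0.0575 with an estimated correlation). NF-kB feedback genes were higher in 6 of 17 cases, or 10 adjusted over the list alone, with Traf1 at 0.52 ± 0.09 (mean 0.31, adjusted p = 4.82e-08, and adjusted p = 0.0739 with an estimated correlation). M2 genes were lower in 3 of 30 cases, Retnla, Mrc1 and Pparg, and higher in 1, or 7 and 2 adjusted over the list alone (mean -0.21, 95% interval -0.30 to -0.12, adjusted p = 0.0377, and adjusted p = 0.15 with an estimated correlation). Without the 5 members whose probes differ between the tables, the M2 mean was -0.14 and the list did not pass (adjusted p = 0.348). Neither did it without SR3335 replicate 1 (-0.19, adjusted p = 0.0779). B cell markers were lower in 3 of 6 cases, or 5 adjusted over the list alone, with Cd79a at -0.93 ± 0.21 (mean -0.57, adjusted p = 8.18e-05, and adjusted p = 0.102 with an estimated correlation). The genes most raised by LPS were higher with SR3335, with a mean of 0.38 and 28 of 100 higher against 1 lower (adjusted p = 2.78e-20). Those most lowered by LPS had a mean of -0.29 (adjusted p = 9.45e-11). Both held with an estimated correlation (adjusted p = 0.00171 and adjusted p = 0.0051). The genes most lowered by IL-4 had a mean of -0.11 (adjusted p = 0.0454, and adjusted p = 0.676 with an estimated correlation). This call was lost without SR3335 replicate 2 (-0.08, adjusted p = 0.172) or SR1078 replicate 1 (-0.10, adjusted p = 0.086). The genes most raised by IL-4 did not pass (mean -0.09, adjusted p = 0.0977). Of the genes named here, Traf1, Cd79a and Retnla did not pass without SR3335 replicate 1, SR3335 replicate 2, SR1078 replicate 1 or SR1078 replicate 2 (adjusted p from 0.065 to 0.223).

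Further lists passed with smaller shifts. Cholesterol synthesis genes had a mean of 0.17 with 1 of 14 higher, or 6 adjusted over the list alone (adjusted p = 0.0135, and adjusted p = 0.105 with an estimated correlation). Interferon-stimulated genes had a mean of 0.12 with 0 of 26 past the threshold, also adjusted over the list alone (adjusted p = 0.00608, and adjusted p = 0.102 with an estimated correlation). Chemokines had a mean of 0.11 with 2 of 14 higher and 1 lower, or 6 and 1 adjusted over the list alone (adjusted p = 0.0394, and adjusted p = 0.218 with an estimated correlation). MHC class I processing genes had a mean of 0.11 with 0 of 15 past the threshold, also adjusted over the list alone (adjusted p = 0.0403, and adjusted p = 0.234 with an estimated correlation). Kupffer cell identity genes had a mean of -0.14 with 2 of 20 lower, or 3 adjusted over the list alone (adjusted p = 0.0316, and adjusted p = 0.234 with an estimated correlation). LXR target genes had a mean of -0.18 with 2 of 11 lower, also adjusted over the list alone (adjusted p = 0.0377, and adjusted p = 0.158 with an estimated correlation). Lysosome genes had a mean of -0.14 with 2 of 18 lower, or 3 adjusted over the list alone (adjusted p = 0.0369, and adjusted p = 0.149 with an estimated correlation). Without SR3335 replicate 2, chemokines (adjusted p = 0.0998), MHC class I (adjusted p = 0.114) and lysosome genes (adjusted p = 0.0701) did not pass, nor did chemokines (adjusted p = 0.0971) and lysosome genes (adjusted p = 0.06) without SR1078 replicate 2. Without SR3335 replicate 1, Kupffer cell identity (adjusted p = 0.0594) and LXR target genes (adjusted p = 0.0761) did not pass. Without SR1078 replicate 1, these 2 lists (adjusted p = 0.0905 and adjusted p = 0.0617) and MHC class I genes (adjusted p = 0.135) did not pass.

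In glycolysis and hypoxia genes no difference between the compounds was detected, with 0 of 17 past the threshold, also adjusted over the list alone (mean 0.07, median -0.01, 95% interval -0.07 to 0.20, adjusted p = 0.294). The same held for cell cycle genes as a list (mean -0.01, 95% interval -0.14 to 0.13, adjusted p = 0.932), where Tk1 was lower (-0.54 ± 0.07) and Ccne1 higher (1.01 ± 0.21) with SR3335, and 1 and 1 passed adjusted over the list alone. Tk1 did not pass without SR3335 replicate 1 (adjusted p = 0.0532), nor Ccne1 without SR3335 replicate 1, SR3335 replicate 2, SR1078 replicate 1 or SR1078 replicate 2 (adjusted p from 0.123 to 0.203). NRF2 target genes had a mean of -0.08 (95% interval -0.32 to 0.15, adjusted p = 0.366). Across genes, the differences of the compounds from vehicle correlated at r = 0.43 (rho 0.43). They share the vehicle arrays, which alone gave r = 0.5 in 100 simulations, and their covariance was 0.0251 against 0.0129 in the simulations. Those simulations used the pooled spread, so 0.0129 may be too high for the vehicle arrays. Of the genes tested, 45 rose with both compounds and 13 fell with both, against 2.25 and 0.916 for independent calls, which the shared arrays also raise.

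With 1 array left out, 60 genes passed without SR3335 replicate 1, 121 without SR3335 replicate 2, 100 without SR1078 replicate 1 and 70 without SR1078 replicate 2. By name, 17 of the 56 named genes passed each time, among them Calb2, Il19 and Pparg but neither Nos2, Il27, Ptges, Ifng nor Retnla. Median centring gave 167 higher and 334 lower (33.3% higher against 45.9%).

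**Figure D4:**
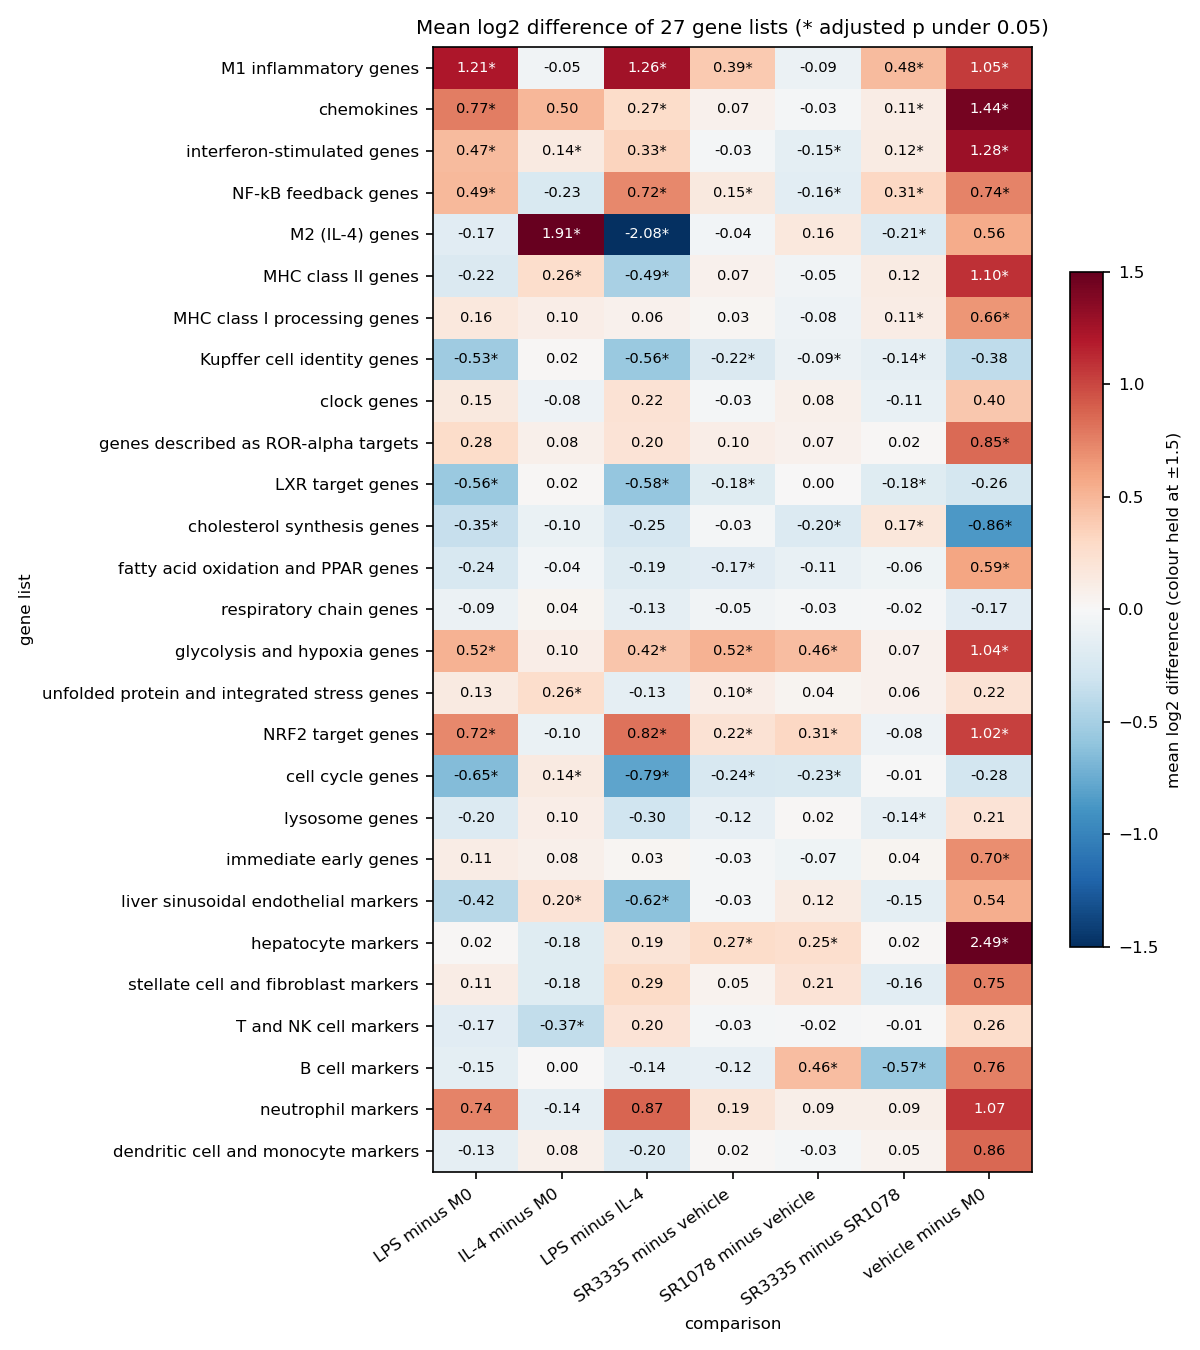
Mean log2 difference (colour and printed value) of 27 gene lists (rows) in the 7 comparisons (columns), with a star where the adjusted p is under 0.05. M1 genes stand at 1.21 in LPS minus M0 and 0.39 in SR3335 minus vehicle, M2 genes at 1.91 in IL-4 minus M0, and glycolysis and hypoxia genes at 0.52 and 0.46 with the compounds.

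Vehicle was compared with M0 to measure how the control arrays of the 2 sets differ. Hepatocyte genes were far higher on the vehicle arrays. Ttr, the plasma carrier transthyretin, was 13.2-fold higher (log2 3.73 ± 0.21, n = 2 arrays per group, adjusted p = 1.17e-06) and the apolipoprotein gene Apoa1 11.3-fold higher (3.50 ± 0.20, adjusted p = 1.35e-06). Inflammatory and interferon-stimulated genes were also higher, with Nos2, undetected in M0, at least 17.5-fold higher (adjusted p = 1.71e-07), Cxcl1 at 3.87 ± 0.16 and Isg20 at 3.41 ± 0.14. Il33 was at least 92.4-fold and the copper oxidase gene Heph at least 116-fold higher, both undetected in M0. Trem2 fell by 3.08 ± 0.07 and Rassf4 by 3.41 ± 0.08. In all, 6549 of 10255 genes passed, 2940 higher and 3609 lower with vehicle, more than in any of the other 6 comparisons.

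By list, 15 of 16 hepatocyte markers were higher and 1 lower, also adjusted over the list alone (mean 2.49, adjusted p = 5.76e-06, and adjusted p = 0.29 with an estimated correlation). Interferon-stimulated genes were higher in 24 of 26 cases and lower in 1, also adjusted over the list alone (mean 1.28, adjusted p = 3.12e-09), and this call held with an estimated correlation (adjusted p = 0.0324). Chemokines were higher in 12 of 14 cases and lower in 1, also adjusted over the list alone (mean 1.44, adjusted p = 7.31e-05, and adjusted p = 0.0769 with an estimated correlation). M1 inflammatory genes were higher in 17 of 26 cases and lower in 2, also adjusted over the list alone, with Il6, undetected in M0, at least 9.59-fold higher (adjusted p = 0.000675, and adjusted p = 0.178 with an estimated correlation). Cholesterol synthesis genes were lower in 10 of 14 cases and higher in 1, also adjusted over the list alone, with Fdps at -1.80 ± 0.08 (mean -0.86, adjusted p = 0.00911, and adjusted p = 0.102 with an estimated correlation). The other lists that passed, all higher with vehicle, had means of 1.10 for MHC class II, 0.66 for MHC class I processing, 0.74 for NF-kB feedback, 1.04 for glycolysis and hypoxia, 1.02 for NRF2 targets, 0.85 for ROR-alpha targets, 0.59 for fatty acid oxidation and PPAR and 0.70 for immediate early genes. Each of these calls was lost with an estimated correlation (adjusted p from 0.102 to 0.234). Markers of other liver cells had means of 1.07 for neutrophils (95% interval 0.77 to 1.38), 0.86 for dendritic cells and monocytes (0.73 to 1.00), 0.76 for B cells, 0.75 for stellate cells and fibroblasts, 0.54 for sinusoidal endothelium and 0.26 for T and NK cells, and these lists did not pass (adjusted p from 0.0822 to 0.377). Klf4 was higher by 2.77 ± 0.17, although 1 of its other kept probes gave 0.08 (adjusted p = 0.71), and Rora by 0.49 ± 0.15 (adjusted p = 0.0179), and both have probes among those that differ between the tables in the set of the vehicle arrays. The Rora call was lost without M0 replicate 1 (0.52, adjusted p = 0.0508), M0 replicate 2 (0.47, adjusted p = 0.0751) or vehicle replicate 1 (0.39, adjusted p = 0.113). The vehicle and M0 groups lie in different array sets and no group lies in both, so this difference and the difference between the sets cannot be told apart. Median centring moved the median of all genes to -0.19 and gave 2504 higher and 4222 lower (37.2% higher against 44.9%).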

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

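All tests in this part, those of the overlap with passing genes included, were chosen only after the result was seen. What drew attention was a difference between the 2 deposited tables. In the authors' processed values, 30 probes differ from what the deposited signals give, and all 30 lie in the set with vehicle, SR3335 and SR1078, against 0 in the set with M0, LPS and IL-4. They belong to 23 named genes and 2 unnamed probes, and among the genes are Rora, Klf4, Arg1, Mrc1, Chil3 and Ccl24.

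Of the 23 differing entries among the genes tested, all 23 passed in IL-4 minus M0, a comparison whose own values do not differ, where 4.5 would by chance (exact hypergeometric test, p = 4.6e-17). In SR1078 minus vehicle 16 passed (0.323 by chance, exact p = 2.2e-25), in SR3335 minus SR1078 12 (1.06 by chance, p = 6.54e-11) and in SR3335 minus vehicle 6 (1.07 by chance, p = 0.000492). These p-values treat genes as independent, which they are not. The comparisons of the compounds also use the very signals that are in doubt, and an altered signal could by itself make a gene pass. For those comparisons randomly drawn genes are no fair chance level, and no conclusion is drawn from the overlaps. For Rora, SR3335 minus vehicle was -1.68 from the background-corrected signals and -0.74 from the processed values, and for Aldh1b1, SR1078 minus vehicle was -1.37 and -0.59. Part of these gaps may come from that correction, which the processed values lack. Normalized as the processed values were, Rora on array 1 of SR3335 was 6.926 from the signals against 7.146. Aldh1b1 on array 1 of SR1078 was 7.54 against 8.096.

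The tables argue against rounding or settings of the quantile normalization, since the smallest of these differences was 5.5 times the largest among all other probes. A candidate explanation is that the signals and detection p values of these probes come from different versions of the data. On the compound arrays, 13 values of 6 probes (of Klf4, Rora, Aldh1b1, Matk and Chil3) had a detection p outside that of the probes with the nearest signals, against 0 values on the vehicle arrays, 0 in the other set and 0 among all other probes. Rora on array 1 of SR1078 had a signal of 350 with a detection p of 0.00501, which on that array belonged to signals of 185 to 200.9. Normalized as theirs, that signal was 8.292, and the authors' value of 8.516 lay further still from those signals. For Aldh1b1 on that array the p of 0 belonged to signals of at least 236.6. Its signal was 203.26, and the authors' value was higher (8.096 against 7.54), in the direction of that p. Neither version matched the detection p for all of these values. The files do not say how or why the values came to differ, or which version is the measured one, and no biological explanation was tested.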

How the results depend on the processing

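Fits of each array set on its own and without the probes that differ between the tables were tests chosen only after the result was seen. Among named genes, 10358 of 11598 values kept their direction and their side of the threshold, 1144 no longer passed, 94 newly passed and 2 reversed. Abca9 in IL-4 minus M0 was 0.00 with the authors' values and Gadd45a in SR1078 minus vehicle was 0.04 without the differing probes, in both cases because another probe then stands for the gene. Of list means outside M1 and M2, 1131 of 1285 stayed and 154 no longer passed. The estimated correlation alone ended 66 of the 69 list calls. Only lists that passed at the preset correlation were entered, so none could newly pass.

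Counts of passing genes stayed within 1.5 times in 77 of 124 cases. Without background correction they were 729 for SR3335 minus vehicle, 370 for SR1078 minus vehicle and 742 for SR3335 minus SR1078, and with the authors' values 948, 520 and 921. Without a filter they were 308, 81 and 300, with a variance trend 743, 373 and 726, and with array weights 1140, 620 and 1061, with 979 for IL-4 minus M0. The saddle method gave 241 and the strict filter 230 for SR1078 minus vehicle. For these the cause was not tested. With only the 2 groups compared, which leaves fewer arrays, counts were 230 for IL-4 minus M0, 1620 for LPS minus IL-4, 265, 20 and 298. Each set on its own gave 2061 for LPS minus M0, 819 for IL-4 minus M0 and 732 for SR3335 minus SR1078. These fits pool the spread within a set only, but they also normalize within it and use fewer arrays. Which of these changed the counts was not tested. Leaving out 1 array gave 1069 to 2665 for IL-4 minus M0, 76 to 143 for SR3335 minus vehicle, 5 to 8 for SR1078 minus vehicle and 60 to 121 for SR3335 minus SR1078.

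The replicate numbers do not pair the arrays (r of -0.0378 to 0.0968 over 15 pairs of groups). With the number as a replicate block, 92 genes passed in SR1078 minus vehicle over all 12 arrays. In fits of the 2 groups alone, the replicate block left 1011 for LPS minus M0, 88 for IL-4 minus M0, 1360 for LPS minus IL-4, 403 for SR3335 minus SR1078 and 6385 for vehicle minus M0. In limma it left 0 for SR3335 minus vehicle (2165 at an unadjusted p under 0.05) and 0 for SR1078 minus vehicle (1986), with 1 residual degree of freedom.

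The M1 mean did not pass with an estimated correlation in SR3335 minus vehicle (0.39) or SR3335 minus SR1078 (0.48). In SR1078 minus vehicle it newly passed without background correction (-0.08), with median centring (-0.08), the strict filter (-0.13), every probe (-0.10), a trend (-0.09) and each set on its own (-0.09), and ranged from -0.14 to -0.04 over arrays left out. The M2 mean newly passed in SR1078 minus vehicle with the authors' values (0.17) and every probe (0.20). In SR3335 minus SR1078 it did not pass with median centring (-0.23), the strict filter (-0.21), an estimated correlation (-0.21), each set on its own (-0.21) and without the differing probes (-0.14), and ranged from -0.22 to -0.19 over arrays left out. The cause was not tested.

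Genes lowered by IL-4 did not pass with an estimated correlation in SR3335 minus vehicle (-0.20) and SR1078 minus vehicle (-0.10). In SR3335 minus SR1078 they did not pass without background correction (-0.05), with the saddle method (-0.07), median centring (-0.15), the authors' values (-0.06), the strict filter (-0.10), and at -0.11 with a trend, the 2 groups alone, the block of 2 groups, an estimated correlation and each set on its own, with -0.13 to -0.08 over arrays left out. Genes raised by IL-4 newly passed in SR1078 minus vehicle without background correction (0.09), with the saddle method (0.10), the authors' values (0.11), no filter (0.11), the strict filter (0.14), every probe (0.13) and a trend (0.11), with 0.08 to 0.13 over arrays left out, and in SR3335 minus SR1078 with no filter (-0.09) and every probe (-0.13). The cause was not tested.

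The correlation of SR3335 with LPS was 0.30 without background correction, with the saddle method, the authors' values and each set on its own, 0.24 without a filter and 0.31 with the strict filter, and 0.24 to 0.28 over arrays left out. That of SR1078 with IL-4 was 0.14 without background correction and with the authors' values, 0.13 with the strict filter and each set on its own, 0.08 without the differing probes, and 0.08 to 0.11 over arrays left out. That of SR3335 with IL-4 was 0.06 to 0.12 over arrays left out. A block by slide was not run because the files name no slide, and the authors' values and separate sets were not run for vehicle minus M0. Signal over background limits dim probes.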

Other observations

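In this part, the tests of array set or preparation and of hepatocyte RNA were chosen only after the result was seen. The correlation of vehicle minus M0 with LPS minus IL-4 was not among the correlations planned beforehand. MHC class II genes were higher on the vehicle arrays in 9 of 10 cases (mean log2 1.10), MHC class I processing genes in 10 of 15 (0.66) and NRF2 target genes in 8 of 12 (1.02), with 1 lower. These list calls (adjusted p = 0.000496, 0.00454 and 0.0189) were lost with an estimated correlation (adjusted p = 0.202, 0.135 and 0.123). The endothelial hyaluronan receptor gene Lyve1 was higher by 4.77 and the iron hormone gene Hamp by 4.67. Mx1, an antiviral gene, was higher by 3.20.

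Across genes, vehicle minus M0 moved with LPS minus IL-4 at r = 0.29. Among the 3419 brightest genes the correlation was 0.33 (95% interval 0.28 to 0.37 over resampled genes). This value argues against a difference in background as the whole cause. The interval treats genes as independent, which they are not, and does not measure the spread between arrays. Array set, preparation of the cells and the vehicle itself stay open and cannot be told apart, since 0 groups lie in both sets. RNA of hepatocytes in the second set may explain the hepatocyte markers, but this was not decided. Of these markers 15 of 16, not all, were above 0, with the abundant transcripts Ahsg at 4.29, Ttr at 3.73 and Apoa1 at 3.50. That count restates the pattern itself, so it cannot tell this explanation from others. The labels name a Percoll step, which would lower the number of hepatocytes.

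With both compounds the glycolysis and hypoxia list was shifted up and the cell cycle list down at the preset correlation of 0.01. All 4 calls were lost with an estimated correlation (adjusted p = 0.0529 and 0.0739 with SR3335, 0.0575 for both lists with SR1078). Chance in the shared vehicle arrays stays open. The 2 vehicle arrays differed by at most 0.104 of the smaller compound shift, but the bound set for this test assumed separate cultures, which nothing states, so their agreement may measure technical noise alone. Of 16 list shifts made with 4 other background corrections or normalizations, 0 lost their call at that preset correlation or their direction in limma, so these steps as the cause are argued against too. An effect of both compounds, or of a handling step shared by the compound arrays, may remain as a hypothesis and was not tested.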
